A study of Mus musculus with 2 samples.

How the data were processed

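H3K9me3 ChIP-seq libraries were made from limbs of mouse embryos at 12.5 days, 2 biological replicates of 1 group with 1 technical replicate each, and a size range of 300 to 500 per the labels. The replicates are pools of different embryos (88 and 68), so the differences between them hold both animal and technical spread. Each replicate had its own list of peaks, and there were 2 lists for the pair, 1 pooled and 1 replicated. All 4 are narrowPeak lists on mm10.

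The lists were called on filtered alignments of a library together with another input file, per the text files deposited with the samples, and the labels name possible controls. The pooled list was derived from both libraries, and the replicated list from both libraries' lists and the pooled list, per the same text files. The aligner, the peak caller, the filters and the rule for a replicated peak are not given in the sources used here. Column 7 of the deposited lists is the authors' fold over background for each peak, a ratio, and column 9 is their q-value on the −log10 scale, −log10 q. Both are values of single peaks, and were used only to describe, rank or filter peaks within a list. The lowest −log10 p was 2.05 in the list of replicate 1, 2.01 in that of replicate 2, 2.09 in the pooled list and 2.09 in the replicated list, so the lists reach down to weak peaks. Every replicated peak was also a line of the pooled list. Of the replicated peaks on chromosomes, 10821 (28.4%) did not overlap a peak of both libraries, so the list is not the overlap of the libraries' lists. Of the pooled peaks left out of it, 475 of 63190 (0.752%) overlapped both. Peak lists hold no read totals. The depth of each library is therefore unknown, and whether the larger number of peaks in replicate 2 comes with greater depth could not be examined.

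The genome was GRCm38.p6, whose chromosome lengths are those of mm10, with lower-case letters for repeat-masked sequence as NCBI provides it (the program is not given in the sources used here). Genes came from the GENCODE vM21 basic annotation, protein-coding and long non-coding RNA genes on 19 autosomes, X and Y. Scaffolds were left out except where named. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and numba 0.67.0, and figures matplotlib 3.10.9. Overlaps were computed in numpy and checked with bedtools 2.31.1, which gave the same numbers of overlapping peaks (difference 0) at 1 bp and at a reciprocal overlap of 50%.

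For the replicates, a peak counted as shared if it overlapped a peak of the other library by at least 1 bp. Chance was measured by rotating the peaks along each chromosome between its first and last known base, 1000 times, which keeps their spacing (two-sided permutation p, at smallest 0.002). The Jaccard index is the shared length over the length covered by either library. For annotation, each base had 1 class, in the order promoter (1 kb either side of a transcription start), coding exon, UTR, other exon, intron and intergenic. The share of replicated peak bases in each of the 6 classes and in masked sequence was compared with the same rotations, with Benjamini-Hochberg adjustment over these 7 tests. For gene lists, a gene counted if its body overlapped a replicated peak by at least 1 bp. Each of 21 lists was compared with 10000 random lists of the same size, drawn from genes of the same biotype in 20 bins of gene length (two-sided permutation p, at smallest 0.0002, Benjamini-Hochberg over the lists, threshold 0.05). The lists were zinc-finger factors, olfactory receptors, vomeronasal receptors, clustered protocadherins, Hox genes, core histones, ribosomal proteins, keratin-associated genes, cytochrome P450 families 2 to 4, serpins A and B, defensins, limb patterning, chondrogenic, myogenic, neuronal, liver and blood, endothelial, epidermal, imprinted, germline and H3K9 methylation machinery. The position within zinc-finger genes was the covered share of the last exon minus that of the first, in the transcript with the longest coding sequence, averaged over genes and compared with 10000 draws of length-matched genes that had a peak. Domains were replicated peaks merged when at most 10 kb apart.

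Genes and regions were named by a rule fixed before the data were examined. It took the 10 replicated peaks of highest fold, the 10 protein-coding genes of at least 2 kb with the largest covered share, up to 4 members of each list with a peak by covered share, and the 10 domains of longest covered length with up to 3 genes each. Predicted genes were named only for peaks and domains. The names of protocadherin groups in the domains follow the annotation.

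The tests were also run on simulated data with known answers. A list of 200 genes with its chance of a peak raised 1.5 times was called in 90 of 100 simulations and one raised 2 times in 100 of 100, over 21938 protein-coding genes, and an unchanged list was called in 6 of 100. For the overlap of replicates, 2 unrelated lists of 2000 peaks were called in 0 of 100 simulations, and lists sharing 5% of their peaks in 100 of 100. For the position within zinc-finger genes, a difference of 10 points in 200 genes out of 4000 was called in 94 of 100 simulations, and no difference in 6 of 100. In these simulations genes and peaks were drawn at random over the genome, and each gene got its value independently. The rates therefore do not cover clustered genes that share peaks, or peaks that lie in clusters. The simulated gene lists held 200 genes, with an unchanged or a raised chance of a peak. Their rates do not cover shorter lists, lists with fewer peaks, or the adjustment over the lists. They give no power for the short lists that were not called.

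Alternatives fixed in advance were other overlap rules (50% of the peak's own length, and reciprocal 50% with 200 rotations), −log10 q of at least 2, a fold of at least 4, autosomes alone, merging within 1 kb, each library's own list, rotation of the genes, at least 10% of the body covered, promoters alone, promoters of 2 kb, and merging distances of 2 and 50 kb. Alternatives chosen after the data were seen were replicated peaks that overlap a peak of both libraries, peaks with at least 4 of 5 evenly spaced 32-mers found once in the genome, and lists without members that overlap another member. Library quality, the input libraries and the read alignments were not analysed here.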

Results

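The histone mark H3K9me3, trimethylation of lysine 9 of histone H3, was mapped by ChIP-seq in the limbs of mouse embryos at 12.5 days. ChIP-seq sequences the DNA fragments that come down with an antibody, here one against H3K9me3, a mark known from silent chromatin. There was 1 group with 2 biological replicates. Replicate 1 was a pool of limbs from 88 embryos and replicate 2 a pool from 68 embryos, both of the C57BL/6-derived strain B6NCrl and of mixed sex. With a single group, the comparisons were those between the replicates and those between the marked regions and the genome. The deposited values were lists of peaks on the mm10 build, each peak with the authors' own fold over background and −log10 q. Peak lists hold no read totals, so the depth of each library is unknown and no counting interval is given.

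The lists of both limb pools held many, mostly short H3K9me3 peaks. Peak width is a property of the calls, and clustered peaks covered longer stretches (below). Replicate 1 had 55739 peaks, of which 55448 lay on assembled chromosomes and covered 17.999 Mb (0.680%). Replicate 2 had 91935 peaks, of which 91603 lay on chromosomes and covered 31.4 Mb (1.19%), so it had 1.65 times as many peaks in all and 1.74 times the length on chromosomes. The median peak was 258 bp wide in replicate 1 and 267 bp in replicate 2, with a median fold of 2.92 and 3.00. The authors' pooled list held 101574 peaks, of which 101253 lay on chromosomes and covered 39.0 Mb. Their replicated list, used for the comparisons with the genome and its genes, held 38298 peaks (37.7% of the pooled list), of which 38063 lay on assembled chromosomes and covered 22.1 Mb (0.836%). The 38298 peaks were wider (median 470 bp, interquartile range 348 to 672) and reached a fold of 14.1 (median 3.22).

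The strongest H3K9me3 peaks were found in both limb pools, and the weakest mostly in 1. Of the 55448 replicate 1 peaks on chromosomes, 30145 (54.4%) overlapped a replicate 2 peak by at least 1 bp, against 2.63% ± 0.311 (SD of 1000 rotations) when the peaks were rotated along their chromosomes. Of the 91603 replicate 2 peaks, 29389 (32.1%) overlapped a replicate 1 peak, against 1.59%. The observed shares were 20.7 and 20.1 times those under rotation (two-sided permutation p = 0.002 for each, the smallest that 1000 rotations can give). The libraries shared 8.96 Mb, which was 49.8% of the length covered in replicate 1 and 28.6% of that in replicate 2. The Jaccard index was 0.222, against 0.00531 under rotation (permutation p = 0.002). With each list cut into 10 equal parts by −log10 q, the overlap fell from 89.3% in the highest part to 36.9% in the lowest for replicate 1, and from 74.9% to 14.9% for replicate 2. Among the 1000 peaks of highest −log10 q, 987 of replicate 1 and 965 of replicate 2 overlapped the other library. Of the 38063 replicated peaks, 27242 (71.6%) overlapped a peak of each library, 8337 (21.9%) a peak of replicate 2 alone, 2206 (5.80%) a peak of replicate 1 alone and 278 (0.730%) neither.

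**Figure D1:**
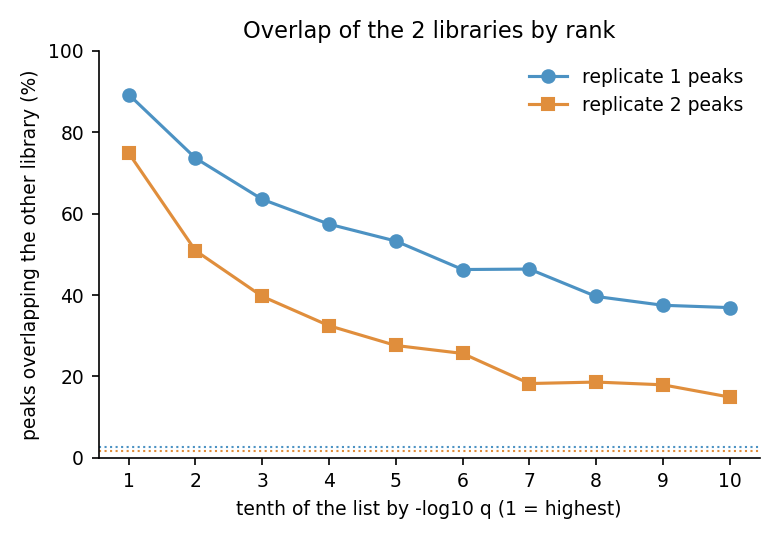
Share of peaks (%, vertical axis) that overlapped a peak of the other library, for 10 equal parts of each list ordered by −log10 q (horizontal axis, 1 is the highest). Circles are replicate 1, squares replicate 2, and dotted lines the means under rotation (2.63% and 1.59%), which lie below every point.

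The replicated peaks lay mostly outside protein-coding and long non-coding RNA genes and were depleted from introns. Pseudogenes and immunoglobulin V genes were not counted as genes here, so intergenic sequence can hold them. Intergenic sequence held 60.7% of peak bases, against 51.7% ± 1.54 (SD of 1000 rotations), and introns 31.95% against 42.3% ± 1.45 (ratios 1.17 and 0.755, adjusted permutation p = 0.00466 for both). Coding exons held 2.23% of peak bases against 1.27% ± 0.0928, a ratio of 1.76 (adjusted permutation p = 0.00466). Exons outside coding sequence and UTRs held 0.551% against 0.407% (ratio 1.35, adjusted permutation p = 0.0252), a call lost with promoters of 2 kb (ratio 1.36, adjusted permutation p = 0.0509). Promoters, 1 kb either side of a transcription start, held 3.10% against 3.00% (adjusted permutation p = 0.643), and UTRs 1.49% against 1.32% (adjusted permutation p = 0.140), neither beyond the spread of the rotations. With replicate 1's own list promoters were called as enriched (ratio 1.14, adjusted permutation p = 0.0448), and with replicate 2's the ratio was 0.930 (adjusted permutation p = 0.207). Repeat-masked sequence held 35.7% of peak bases against 33.7% ± 0.627 (ratio 1.06, adjusted permutation p = 0.0140). These 7 tests were adjusted together. With replicate 1's own list the masked share was not called (ratio 1.03, adjusted permutation p = 0.166), and with peaks present in both libraries it was not called either (ratio 1.04, adjusted permutation p = 0.0839). Of rotated positions, 6.07% had none of their sampled 32-mers unique in the genome, against 0.147% of replicated peaks. The ratio for masked sequence does not allow for this difference.

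Of 21 gene lists fixed before the data were examined, 7 carried replicated peaks more often than length-matched genes, 0 less often, and 14 were not called. When the genes were rotated along their chromosomes, which allows for clustering, 5 of the 7 were called, without the olfactory receptors (adjusted permutation p = 0.791) and the P450 genes (adjusted permutation p = 0.415). In all, 4844 of 21938 protein-coding genes (22.1%) and 1431 of 10155 long non-coding RNA genes (14.1%) had a replicated peak in their body. With replicate 1's own peaks the shares were 29.4% and 18.4%, and with replicate 2's 35.8% and 25.2%. Each list was set against 10000 random lists of the same size and gene lengths, with p adjusted over the 21 lists. The lists of zinc-finger factors, vomeronasal receptors, clustered protocadherins, imprinted genes and germline genes shared the smallest permutation p the draws can give (0.0002), which the adjustment raised to 0.00084. Hox, core histone, keratin-associated, and liver and blood genes had 0 with a peak, against 2.33 to 3.29 expected. This lowest possible count did not pass (adjusted permutation p = 0.131 to 0.298), so these lists could not be called as having fewer. The absence of such calls does not show that no list was depleted.

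**Figure D2:**
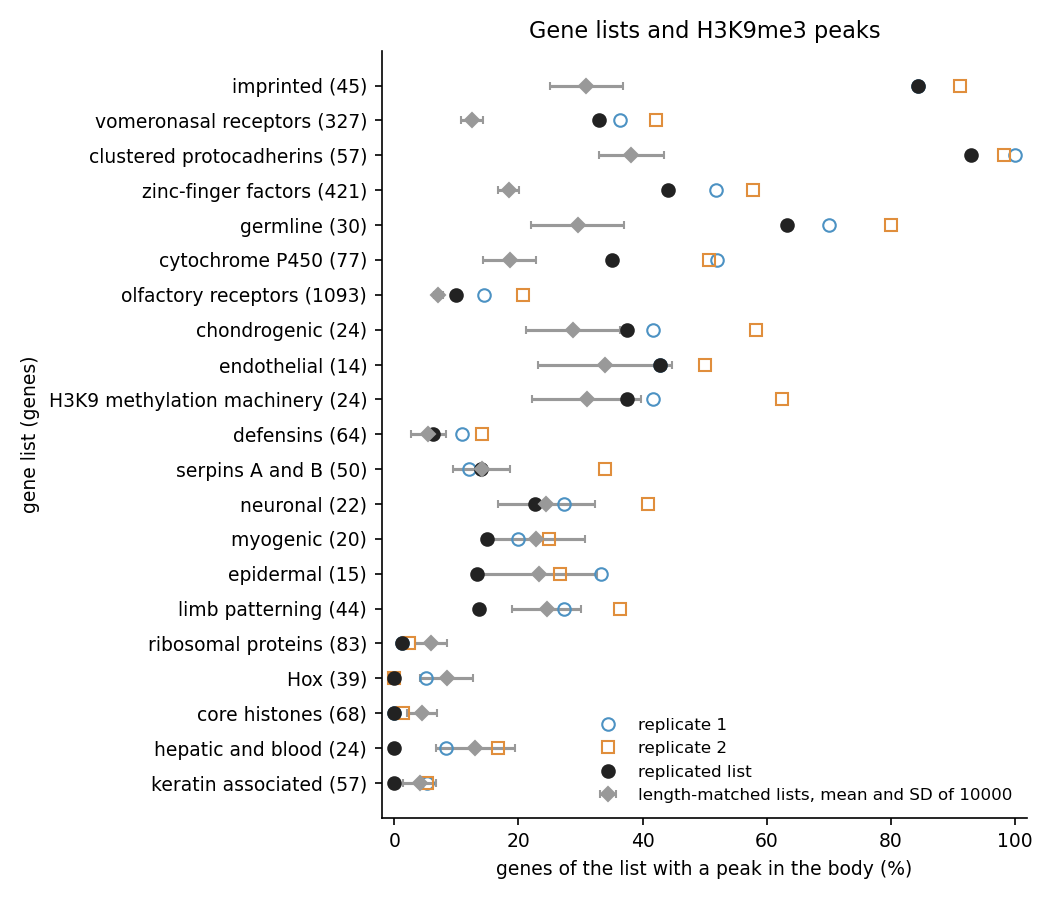
Share of each list's genes with a peak in the gene body (%, horizontal axis) for the 21 gene lists (vertical axis, number of genes in brackets). Black circles are the replicated list, open circles replicate 1, open squares replicate 2, and grey diamonds the mean of 10000 length-matched lists with their SD. The imprinted genes have the same share in the replicated list and in replicate 1 (84.4%), so the black circle covers the open one. Imprinted genes and protocadherins lie far to the right of their matched lists. Hox genes, core histones, keratin-associated genes, and liver and blood genes have 0% in the replicated list.

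Genes for zinc-finger transcription factors, many of them KRAB repressors that lie in clusters, carried replicated peaks more often than matched genes, and those with a peak were covered more in the last exon than in the first. Of 421 such genes, 186 (44.2%) carried a replicated peak, against 18.4% ± 1.72 (SD) in matched lists, a ratio of 2.40 (adjusted permutation p = 0.00084). In the libraries' own lists 218 genes had a peak in replicate 1 and 243 in replicate 2. Zfp110 on chromosome 7 (12834761 to 12850577) was 88.2% covered, Zfp873 on chromosome 10 (82048123 to 82064745) 86.9%, Zfp146 on chromosome 7 (30161269 to 30169750) 79.6% and Zfp68 on chromosome 5 (138603652 to 138619761) 78.5%. In each of these 4 genes the first exon was not covered, and the last exon was covered by 91.6% to 100%. Over the 182 multi-exon zinc-finger genes with a peak, the last exon, which commonly codes for the zinc-finger array, was 40.3% covered and the first exon 4.58%. The mean difference was 35.7 percentage points (SD over genes 43.1), against 0.722 ± 2.08 for draws of matched genes with a peak (permutation p = 0.0002). The value 2.08 is the SD of the draws' means, not a spread over genes, so it is not comparable with 43.1. The last exon was covered more in 126 genes, the first exon in 7, and 49 had no difference. Of 3 equal parts of the gene body, the last was 27.2% covered and the first 7.23% (difference 20.0 points, permutation p = 0.0002). The matched genes were not matched by covered share or exon length. At least 10% of the body was covered in 21.4% of zinc-finger genes, against 2.64% in matched lists. Genes with little coverage can show little difference, so these p-values do not separate position from heavier coverage. The counts of 126 and 7 genes are within the zinc-finger genes alone.

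The clustered protocadherins, cell-surface adhesion genes best known from neurons, were the list with the largest marked share. Of 57 genes, 53 (93.0%) carried a replicated peak against 38.2% ± 5.19 (SD) in matched lists (ratio 2.43, adjusted permutation p = 0.00084), as did 57 genes in replicate 1 and 56 in replicate 2. Pcdhb15 (chromosome 18, 37473540 to 37476340) was 87.2% covered, Pcdhb13 77.7%, Pcdhb22 75.2% and Pcdhb2 73.9% (43.9% in replicate 1). Many protocadherin genes overlap and share the same peaks. With 1 gene kept per overlapping group, all 23 that were left had a peak, 8.78 times the matched mean of 11.4% (adjusted permutation p = 0.0007). These 23 genes still lie in the same clusters, and the draws treat them as independent. When the 57 genes were rotated along their chromosome, which allows for clustering, the ratio was 2.21 (adjusted permutation p = 0.0168).

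**Figure D3:**
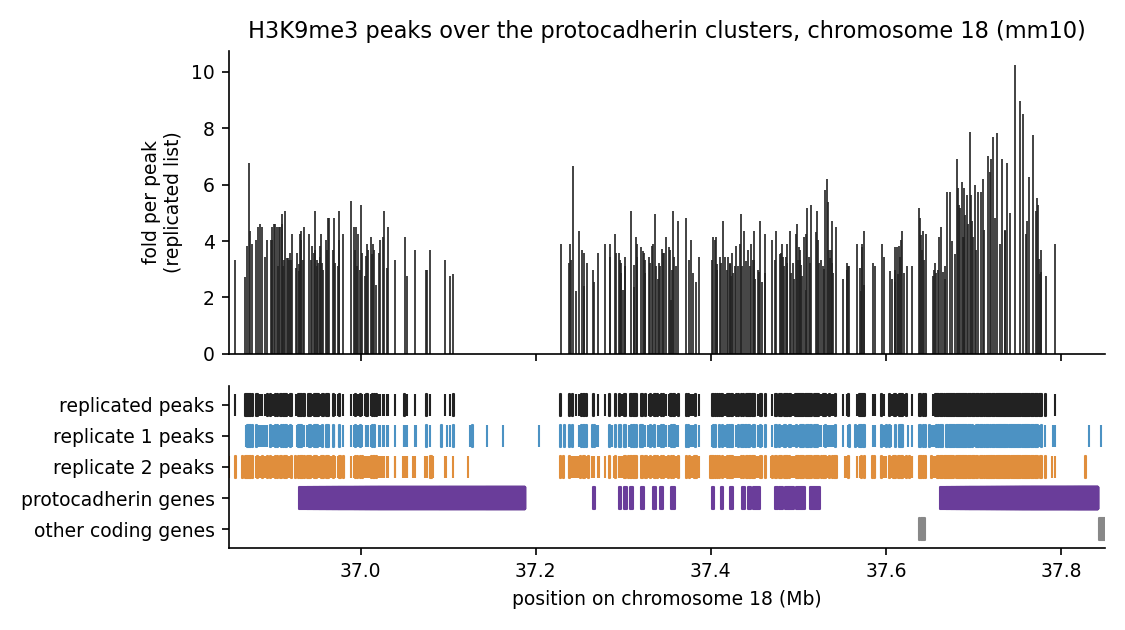
Replicated peaks over the protocadherin clusters of chromosome 18 (position in Mb, mm10, horizontal axis). The upper panel gives the authors' fold of each replicated peak, highest at 10.2 near Pcdhga10, and the lower panel the peaks of the replicated list and of each library with the protein-coding genes. Both libraries have peaks over all 3 groups of protocadherin genes.

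Chemosensory receptor genes and cytochrome P450 genes were also marked more often than matched genes. Of 327 vomeronasal receptor genes, which encode pheromone receptors, 108 (33.0%) had a replicated peak against 12.6% ± 1.75 (SD), a ratio of 2.63 (adjusted permutation p = 0.00084), and 119 had one in replicate 1 and 138 in replicate 2. In the replicated list the most covered were Vmn1r65 (44.6%), Vmn1r66 (43.3%), Vmn1r70 (38.7%) and Vmn1r67 (34.4%), all on chromosome 7. Vmn1r66 was 23.7% covered in replicate 1 and 24.5% in replicate 2, in both less than the other 3. Of 1093 olfactory receptor genes, 108 (9.88%) had a peak against 7.08% ± 0.720 (ratio 1.40, adjusted permutation p = 0.0036), and 158 had one in replicate 1 and 226 in replicate 2. Olfr356 was 66.98% covered (58.9% in replicate 1 and 56.4% in replicate 2) and Olfr1453 54.1% (38.2% and 25.6%). Of 77 genes for cytochrome P450 families 2 to 4, oxidising enzymes found mainly in the liver, 27 (35.1%) had a peak against 18.6% ± 4.29 (ratio 1.89, adjusted permutation p = 0.0021), and 40 had one in replicate 1 and 39 in replicate 2. Cyp3a11 was 34.1% covered, Cyp3a16 27.1%, Cyp3a57 25.3% and Cyp3a25 23.2%, all in the Cyp3a cluster of chromosome 5. Replicate 1 covered less of these 4 genes (16.8%, 16.2%, 13.8% and 11.4%) than replicate 2 (39.4%, 27.7%, 27.3% and 28.1%). These genes lie in clusters, and when the genes were rotated along their chromosomes, the olfactory receptors (ratio 1.13, adjusted permutation p = 0.791) and the P450 genes (ratio 1.43, adjusted permutation p = 0.415) were no longer called. The vomeronasal receptors were (ratio 1.87, adjusted permutation p = 0.0105).

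Imprinted genes, expressed from 1 parental copy, and genes used in germ cells carried replicated peaks more often than matched genes. Of 45 imprinted genes, 38 (84.4%) had a replicated peak against 30.9% ± 5.89 (SD), a ratio of 2.73 (adjusted permutation p = 0.00084). The gene counts were 38 in replicate 1 and 41 in replicate 2. Nnat (chromosome 2, 157560078 to 157562522) was 87.7% covered, the growth inhibitor Cdkn1c (chromosome 7, 143458339 to 143461050) 78.4%, Magel2 (chromosome 7) 71.04% (42.9% in replicate 1) and Peg13 (chromosome 15) 65.2%. Of 30 germline genes, 19 (63.3%) had a peak against 29.5% ± 7.56 (ratio 2.14, adjusted permutation p = 0.00084), with 21 in replicate 1 and 24 in replicate 2. Taf7l (chromosome X, 134460118 to 134476490) was 10.7% covered with its first exon covered in full, and Sycp3, a component of the meiotic synaptonemal complex (chromosome 10, 88459569 to 88473236), 6.19% with its first exon covered in full. The body of Sycp3 was 5.82% covered in replicate 1 and had no peak in replicate 2. Tdrd6 was 4.86% covered, and Rpl10l, a testis ribosomal protein gene, 27.96%. Peaks lay in the promoter of 15 of the 30 germline genes, 19.3 times the matched mean, and of 20 of the 45 imprinted genes, 16.5 times (adjusted permutation p = 0.00084 for both). With at least 10% of the body required to be covered, 2 of 30 germline genes (6.67%) were left against 2.13% in matched lists. They were not called (ratio 3.13, adjusted permutation p = 0.623), and a ratio from 2 genes cannot show whether the excess holds at this setting.

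The number of limb patterning genes with a replicated peak did not pass the test. Of 44 limb patterning genes, 6 (13.6%) had a peak against 24.6% ± 5.56 (SD) in matched lists (ratio 0.554, adjusted permutation p = 0.133), and 0 had one in the promoter. The libraries' own lists lay closer to their matched lists, with 12 genes in replicate 1 (ratio 0.845, adjusted permutation p = 0.730) and 16 in replicate 2 (ratio 0.940, adjusted permutation p = 0.996). Bmp7 was 2.08% covered (1.27% in replicate 1 and 2.30% in replicate 2), Prrx1 1.14% (0.755% and 1.15%), Fgfr2 0.598% (0.423% and 0.859%) and Wnt7a 0.542% (0.532% and 0.851%). The body of Fgfr2 spans 2960900 bp in this annotation, so its covered share is small although 32 peaks lie within that span. None of them covered its promoter, or the first or last exon of the transcript used. Of 39 Hox genes 0 had a peak (3.29 expected, adjusted permutation p = 0.133). The list of replicate 2 alone also had 0, where the test passed (adjusted permutation p = 0.00525), and that of replicate 1 had 2 (adjusted permutation p = 0.416). Of 24 chondrogenic genes 9 had a peak (6.90 expected, adjusted permutation p = 0.567), with Matn4, a cartilage matrix protein gene, 15.0% covered (7.12% in replicate 1) and Col2a1 1.75%. Of 20 myogenic genes 3 had one (4.58 expected, adjusted permutation p = 0.648), namely Ttn, Pax7 and Myh8. In replicate 1 and replicate 2 alone, 10 and 14 chondrogenic genes and 4 and 5 myogenic genes had a peak, without a call.

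Marker genes of other cell types were not called either. A replicated peak lay in 5 of 22 neuronal genes (5.39 expected, adjusted permutation p = 1), 6 of 14 endothelial genes (4.75 expected, adjusted permutation p = 0.708), 2 of 15 epidermal genes (3.51 expected, adjusted permutation p = 0.648) and 0 of 24 liver and blood genes (3.13 expected, adjusted permutation p = 0.131). In replicate 1 and replicate 2 alone the counts were 6 and 9 neuronal, 6 and 7 endothelial, 5 and 4 epidermal, and 2 and 4 liver and blood genes, without a call. Housekeeping and other clustered families gave 0 of 68 core histone genes (3.04 expected, adjusted permutation p = 0.148), 1 of 83 ribosomal protein genes (4.89 expected, adjusted permutation p = 0.148), 0 of 57 keratin-associated genes (2.33 expected, adjusted permutation p = 0.298), 7 of 50 serpins (7.05 expected, adjusted permutation p = 1) and 4 of 64 defensins (3.52 expected, adjusted permutation p = 1). The ribosomal protein gene with a peak was Rpl10l, which is also in the germline list. In the list of replicate 1 alone (1 gene, adjusted permutation p = 0.0184) and of replicate 2 alone (2 genes, adjusted permutation p = 0.0266) the ribosomal protein genes were called as having fewer. Of 24 genes for writers, readers and erasers of H3K9 methylation and their partners, 9 had a peak (7.45 expected, adjusted permutation p = 0.708), among them Atf7ip (4.87% covered), Hells (3.21%, and 2.11% in replicate 1) and Setdb1 (3.01%, and 1.87% in replicate 1). Of the 24, 10 had a peak in replicate 1 and 15 in replicate 2, again without a call.

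Chromosome 7 was the most densely marked chromosome and X was marked far less than any autosome. Chromosome 7 had 37.0 replicated peaks per Mb, against 15.6 over all autosomes, a ratio of 2.37, and held 13.8% of the replicated peaks on chromosomes. The ratio was 2.29 in replicate 1 and 2.00 in replicate 2. Chromosome 17 followed with 28.4 per Mb, and chromosome 14 was the lowest autosome with 8.91. Chromosome X had 3.83 per Mb, 0.245 of the autosomal density (0.419 in replicate 1 and 0.388 in replicate 2), and chromosome Y 0.182. The value for Y rests on 16 peaks over 88.1 Mb. The share of unique sequence is given for X alone (below), so how far it limits peaks on Y is left open. Chromosomes are not replicates, so no test was made.

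**Figure D4:**
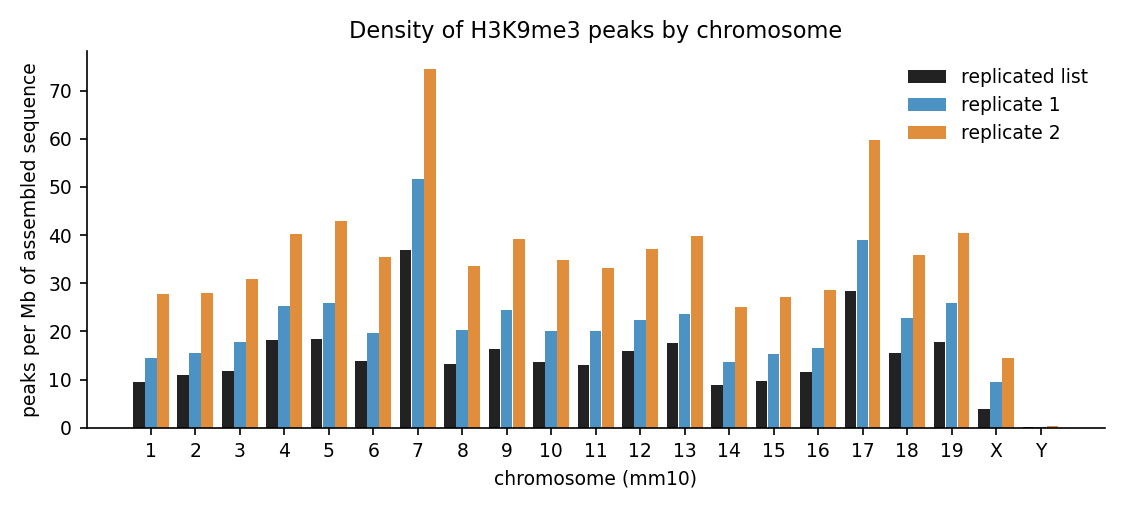
Peaks per Mb of assembled sequence (vertical axis) on each chromosome (horizontal axis, mm10) in the replicated list (black), replicate 1 (blue) and replicate 2 (orange). In all 3 lists chromosome 7 is highest, and X lies below every autosome.

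Clustered peaks covered long stretches, in the 10 domains of longest covered length mostly around members of gene families. Merging replicated peaks at most 10 kb apart gave 20055 domains, of which 385 held at least 10 peaks, 89 of these on chromosome 7 and 59 on chromosome 17. With merging within 2 kb 121 domains held at least 10 peaks, and within 50 kb 378. The 10 domains of longest covered length held 4.74% of all covered sequence, and 5 of them lay on chromosome 7. These values depend on the merging distance, with 1.74% and 2 on chromosome 7 at 2 kb, and 11.1% and 4 at 50 kb. The longest covered length was 190723 bp, against 101173 bp at 2 kb and 395175 bp at 50 kb. The first, on chromosome 18 (37401448 to 37782613), lay over a part of the beta and gamma protocadherins (Pcdhb9 to Pcdhb22 and Pcdhga1 to Pcdhga12) with 184 peaks, and the ninth, on the same chromosome (36867670 to 37039458), over most of the alpha protocadherins (Pcdha1 to Pcdha12) with 90 peaks. In both, the genes of longest covered length were the long predicted genes Gm42416, Gm37013 and Gm37388, which run through the clusters. On chromosome 7, the domain at 17854578 to 18201621 held Gm44613, Gm5155 and the adhesion gene Ceacam12 (181 peaks, 141 kb covered). Neighbouring domains at 33389605 to 33765076 and 33775268 to 34056942 held Gm12763 and the secretoglobin genes Scgb2b24, Scgb2b21, Scgb2b27, Scgb2b26 and Scgb1b27 (163 and 115 peaks). Further domains of chromosome 7 held Vmn1r73, Vmn1r72 and Vmn1r74 (11660811 to 12031656, 153 peaks) and the oocyte genes Nlrp5 and Nlrp4e (23334138 to 23478447, 78 peaks). The other 3 lay on chromosome 4 around Gm12887 (121468989 to 121735544, 131 peaks), on chromosome 12 with no protein-coding or long non-coding RNA gene (114245732 to 114484925, 111 peaks), and on chromosome 13 around Gm49352, Gm49357 and the cathepsin gene Ctsm (61473618 to 61688753, 99 peaks).

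The replicated peak of highest fold lay in the coding exon of Klf14, a single-exon zinc-finger factor gene (chromosome 6, 30956222 to 30959126, fold 14.1). Among the named genes of at least 2 kb, Klf14 was also the second most covered (97.7%), after Scgb2b24 (100%) and before Scgb2b3 (97.6%). Next came Mroh2a (96.4%), Scgb2b27 (95.7%), the bilirubin-conjugating enzyme Ugt1a1 (94.8%), the melatonin synthesis enzyme Asmt (93.9%), the interleukin 3 receptor subunit Il3ra (89.6%), Zfp110 (88.2%) and Nnat (87.7%). There was 1 predicted gene that ranked above Nnat and was not named. In these 10 genes replicate 1 covered between 66.9% and 100% of the body, and replicate 2 between 70.6% and 96.0%. Other peaks of high fold lay in coding exons of Pcdhga10 (fold 10.2) and Zfp810 (chromosome 9, 22278095 to 22281189, −log10 q 53.6), in a UTR of Tcfl5 (chromosome 2, 180642636 to 180643914, fold 10.1) and in an intron of Ccdc106 (chromosome 7, 5028139 to 5033103, fold 9.77). Intergenic peaks lay on chromosome 16 nearest Gm49504 (3233337 to 3237411, fold 10.9), on chromosome 12 (17903381 to 17904199, fold 9.89, nearest Hpcal1 at 111448 bp) and on chromosome 13 nearest Dcdc2a (25049260 to 25050820, fold 9.51) and Gm40841 (28339424 to 28339955, fold 9.43). The peak of second highest fold (11.8) lay on an unlocalised scaffold of chromosome 4.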

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

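Peaks on scaffolds stood outside all comparisons and were counted because the data there had not been used. The replicated list held 235 peaks on unlocalised and unplaced scaffolds, on 24 of 44 scaffolds, and replicate 1 and replicate 2 held 291 and 332. They covered 273 kb, 5.12% of the 5.33 Mb of scaffold sequence, against 0.836% of the assembled chromosomes. Their median fold was 3.65, against 3.22 for the whole replicated list, and the scaffold with the most peaks held 56. The input libraries were not analysed here, so these peaks were not compared with a control.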

How the results depend on the processing

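Of the comparisons under other settings, 240 kept their direction and side of the threshold or moved little, 16 turned to the other side of 1, 17 moved, 6 lost a call and 4 gained a call. The overlap of the replicates, the zinc-finger position and the zinc-finger, vomeronasal, protocadherin and imprinted lists were called under every setting run. The settings with peaks in both libraries, unique 32-mers and no overlapping members were chosen after the data were seen. The causes of the changes below were not tested. At −log10 q of at least 2 replicate 1 kept 20280 peaks and replicate 2 kept 51773, and at a fold of at least 4 the lists kept 3994 (replicate 1), 9698 (replicate 2), 5557 (pooled) and 5527 (replicated). Without one replicate, the ratio to rotation ranged from 0.997 to 1.08 for UTRs, from 0.930 to 1.14 for promoters (adjusted permutation p = 0.0448 without replicate 2) and from 1.03 to 1.08 for masked sequence (adjusted permutation p = 0.166 without replicate 2). Masked sequence had 1.04 with peaks in both libraries (adjusted permutation p = 0.0839), and other exons 1.36 with promoters of 2 kb (adjusted permutation p = 0.0509). Rotating the genes ended the calls of olfactory receptors (1.13) and P450 genes (1.43), and requiring 10% coverage that of germline genes (3.13, 2 genes). Lists with fewer peaks numbered 2 without replicate 1 (Hox and ribosomal proteins) and 1 without replicate 2 (ribosomal proteins), against 0. The ratio of X to the autosomes ranged from 0.388 to 0.419 without one replicate, and merging within 50 kb gave 11277 domains. Merging within 2 kb gave 121 domains of at least 10 peaks (385 at 10 kb). The longest covered length was 101173 bp at 2 kb and 395175 bp at 50 kb (190723 bp at 10 kb), the first 10 domains held 1.74% and 11.1% of covered sequence (4.74% at 10 kb), and 2 of them lay on chromosome 7 at 2 kb (5 at 10 kb). Among lists without a call, the ratio to matched lists without one replicate ranged from 0.597 to 1.33 for serpins, 0.843 to 1.06 for neuronal, 0.977 to 1.01 for endothelial, 0.887 to 1.11 for keratin-associated and 0.720 to 1.08 for epidermal genes. Defensins had 0.588 at −log10 q of at least 2 and 0.347 with peaks in both libraries, where the H3K9 machinery had 0.827. At 10% coverage endothelial genes and the H3K9 machinery had 0, and in promoters serpins had 1.51, and chondrogenic and endothelial genes 0. Serpins had 1.07 without overlapping members. No paired analysis was possible because there is 1 group. Depth is unknown, so what depth limits in either list cannot be stated.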

Other observations

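Families outside the fixed lists, the contents of the domains, their rank by fully unique peaks, the share of unique sequence on X and the copy number of X were examined with tests chosen after the results were seen. Among 245 further families of at least 10 protein-coding genes that share a symbol stem, 3 carried replicated peaks more often than length-matched genes and 0 less often. Even the Pex genes with 0 of 17 (20.3% expected) were not called (adjusted permutation p = 0.501), so small families could hardly be called as having fewer. Secretoglobin genes, which encode small secreted proteins, had peaks in 11 of 34 against 4.55% expected (ratio 7.11, adjusted permutation p = 0.0245), and 11 had one in each library's own list. Ceacam adhesion genes had peaks in 9 of 15 (against 11.8% expected, ratio 5.07, adjusted permutation p = 0.0245), and the natural killer receptor genes Klra in 7 of 11 (against 16.3% expected, ratio 3.91, adjusted permutation p = 0.0490). Under rotation of the genes the ratios were 4.90, 3.01 and 3.65 (unadjusted permutation p = 0.0240, 0.0340 and 0.0480). The domain of chromosome 12 that held no counted gene (114245732 to 114484925) lay over 14 immunoglobulin heavy chain V genes and 7 V pseudogenes.

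Endogenous retroviruses start their copying at a primer binding site that matches a transfer RNA, and H3K9me3 is a known mark of such elements. The hypothesis that limb H3K9me3 lies at these elements predicted that sites matching 3 transfer RNAs would lie within 1 kb of replicated peaks more often than under rotation. Of 174 sites for the proline transfer RNA, 56 did (32.2% against 2.62%, 12.3 times). For phenylalanine 211 of 1090 sites did (19.4% against 3.14%, 6.16 times), and for lysine 21 of 62 (33.9% against 3.27%, 10.4 times). Each had the smallest p that 1000 rotations can give (permutation p = 0.002), and the highest share in any rotation was 8.05%, 5.32% and 14.5%. In replicate 1 the shares were 31.0%, 19.4% and 29.03%, and in replicate 2 38.5%, 32.9% and 50%. This is consistent with H3K9me3 at a part of these elements. Rotation moves the sites to any sequence, so the test does not separate these sites from other retroviral sequence. Only 0.147% of replicated peaks had no unique sampled 32-mer, against 6.07% of rotated positions. Whether peaks could be called at repeated copies is not known, so a site without a peak may still carry the mark.

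Zinc-finger genes carried replicated peaks 2.40 times as often as matched genes. Reads shared between near-identical copies could give peaks in such a family. With peaks of at least 4 unique 32-mers out of 5 the ratio was 2.35 (174 of 421 genes, adjusted permutation p = 0.00084). This argues against shared reads as the whole cause, for copies that share most 32-mers of a peak. The filter kept peaks in which 1 of the 5 was repeated. All 5 were unique in 59.8% of the peaks in zinc-finger genes, against 66.2% of all replicated peaks and 68.8% of rotated positions. Clustering of the genes on the chromosomes could also raise the count, but under rotation of the genes the ratio was 1.94 (permutation p = 0.002), which argues against clustering as the whole cause. The design has 1 group, so no biological explanation was tested.

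Most of the 10 largest domains held several genes or pseudogenes of 1 family, where reads could be placed in the wrong copy. The domain of chromosome 4 held 4 genes, of which 1 was protein-coding and 2 were pseudogenes. Of their 1305 peaks, 97.2% had at least 3 unique 32-mers out of 5, but so had 97.005% of all replicated peaks and 87.4% of rotated positions, so this test cannot decide. Of the sampled 32-mers, 89.2% were unique in these domains, 90.3% over all replicated peaks and 84.5% at rotated positions, and the peaks with all 5 unique made up 61.0%, 66.2% and 68.8%. With only peaks of all 5 unique 32-mers counted, 9 of the 10 domains stayed among the 10 of longest covered length, and the domain of chromosome 13 ranked 11. This argues against read placement among sequences that share exact 32-mers as the whole source of the domains. Read placement between copies that differ by a few bases stays open, because 32-mers that differ by 1 base count as unique. No biological explanation was tested.

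Chromosome X held 0.245 of the autosomal density of replicated peaks. Less unique sequence on X is argued against as the whole cause, since the ratio of unique shares was 0.823. X did hold less unique sequence (69.8% of its 32-mers against 84.8% on the autosomes), so a part in the difference stays open. Fewer clusters on X are also argued against as the whole cause, since the density of peaks in domains of 1 or 2 peaks was 2.40 per Mb on X, 0.277 of the autosomal 8.67 and below the lowest autosome (7.27). A lower copy number of X in pooled male and female embryos, which could leave fewer peaks past a threshold, stays open, because the libraries' depths are unknown. The ratio was 0.419 in replicate 1 and 0.388 in replicate 2, which had 1.65 times as many peaks, so it did not rise in the longer list. The number of peaks is not a measure of depth.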
